A study of Rattus norvegicus with 4 samples.

How the data were processed

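Samples were 4 libraries of primary rat microvascular cells from subcutaneous soft connective tissue. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was taken with oligo(dT) beads, fragmented and reverse transcribed with random hexamers, amplified by PCR and read in pairs on a DNBSEQ-T7 instrument. No molecular identifiers are mentioned, and no strand-marking step, so reads of overlapping genes on opposite strands may not have been separated. Library groups were taken from the sample titles: soft matrix, soft matrix with A83-01, stiff matrix, and stiff matrix with A83-01, 1 library each. Whether the cells of the 4 libraries came from the same animals or the same preparation is not given in the sources used here.

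The deposited table holds a whole-number read count per gene and library, not normalised, which the authors made. A second deposited table holds an FPKM value per gene and library, made by the authors, which scales the counts by transcript length and library size. HISAT2, edgeR and the genome build Rnor_6.0 are named per the submitters' processing notes. The read counter, the annotation and the versions are not given in the sources used here. For 10648 genes with at least 100 counts in every library, the length implied by the ratio of count to FPKM was constant across libraries within 5% for 93.4%. The table has 23608 gene entries. Of these, 1563 carry names of assembled transcripts without a gene name, of which 828 reached the expression minimum, and they held 1.81%, 1.78%, 1.99% and 1.93% of counts in soft, soft with A83-01, stiff and stiff with A83-01. A further 284 carry Ensembl identifiers, of which 0 matched the reference gene table by identifier, and 16541 carry a symbol found there. The reference table has assembly GRCr8 and was used for names only, since its build differs from that of the table. No coordinates are given. No 2 libraries held identical counts.

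Depth was 32475473, 32271844, 33178552 and 33416200 total counts in soft, soft with A83-01, stiff and stiff with A83-01, over 16727, 16626, 16128 and 16526 genes with at least 1 count. Trimmed mean of M-values (TMM) factors, computed over all 4 libraries, were 1.03, 1.04, 0.876 and 1.07. Ribosomal protein genes held 3.77%, 3.51%, 4.39% and 3.79% of counts. Genes with at least 1 TMM-normalised CPM in at least 1 library were kept (13634).

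Calculations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. For each pair of libraries, the log2 ratio of TMM-normalised CPM with a prior count of 2 was taken, with the 95% conditional binomial (Clopper-Pearson) interval of the ratio of counts. A gene was counted as at least 2-fold apart when its ratio reached 2 and the interval excluded a ratio of 1. The pairs were stiff against soft, the same with A83-01 in both, A83-01 against none on stiff, and A83-01 against none on soft. The difference between both inhibitor responses was given with a counting interval by the delta method. A fold against a library with 0 counts was computed against a floor of 3 counts in that library and is a lower bound. Such intervals and floors cover counting error only.

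The tested comparison was edgeR's quasi-likelihood test in an additive model of stiffness and inhibitor over all 4 libraries, with 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. Its common dispersion was 0.0351, a biological coefficient of variation of 0.187. In this model a response to one factor that depends on the other counts as spread, and p-values measure the spread between these libraries. DESeq2 gave 0 missing adjusted p-values. Simulations of unchanged groups drew 20 sets of negative binomial counts with that model's dispersions. Since these come from the same residual as the interaction, the simulated number for the interaction (1255 past 2-fold and 88.3 past 4-fold) is circular and bounds nothing. The simulated numbers for the library pairs use the same dispersions. They do not measure the spread between replicate libraries, which this series does not hold.

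In total, 26 gene lists were fixed before the data were examined, as were the comparisons, tests, thresholds, processing alternatives and the rule for named genes. The lists were TGF-beta response, BMP and ID response, contractile and myofibroblast, fibrillar matrix and crosslinking, basement membrane, matrix proteases and inhibitors, YAP and TAZ targets, focal adhesion, paracrine ligands, Notch pathway, mesenchymal transition regulators, inflammatory cytokines and adhesion, interferon response, cell cycle, hypoxia and glycolysis, cholesterol synthesis, immediate early and heat shock, and markers of endothelial, pericyte and mural, fibroblast, lymphatic endothelial, adipocyte, leukocyte and macrophage, skeletal muscle, keratinocyte, and Schwann cell and nerve origin. A list needed 5 members. Its median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. It was described as standing apart in the top or bottom 2.5%, as a description of these libraries without a p-value. Some genes belong to more than 1 list.

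Named genes were, in each pair, the 8 highest and 8 lowest genes with a symbol by the interval bound nearest to a ratio of 1, up to 4 members of each list with the largest log2 ratios, and a fixed set of 15 genes, among them Acta2, Tagln, Cnn1, Smad7, Pdgfrb, Rgs5, Cspg4, Cdh5, Pdgfb, Edn1, Col1a1, Ctgf, Mki67 and Pecam1, the last of which has no entry under that name and was not analysed here. In the additive test the 5 genes with a symbol of smallest adjusted p per direction were added, and for the difference of responses the 5 highest and 5 lowest. List members named as passing or not passing the additive test, and other genes used as examples of a count, were chosen after their values were seen.

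The calculations were tested on simulated counts for the 13634 genes with 200 genes changed. With Poisson counts, 95.5% of the counting intervals of stiff against soft held the true ratio. With the dispersion of the additive model 38% did, so an interval that covers counting error only is much narrower than the spread in that model. That spread includes any response to one factor that depends on the other. The quasi-likelihood test recovered 58%, 86%, 94% and 100% of simulated 2-fold, 3-fold, 4-fold and 8-fold changes for stiffness, and 56%, 86%, 94% and 100% for the inhibitor, with 9 unchanged genes called in each. No simulated response to one factor depended on the other. These percentages therefore do not give the recovery of real genes with such a response, which may be lower. Of 200 random lists, 4% stood apart.

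Alternatives tried were DESeq2 median-ratio size factors, upper quartile factors and total counts as scaling, no expression filter, a minimum of 5 CPM, prior counts of 0.5 and 10, the deposited FPKM as log2(FPKM + 0.1), fold thresholds of 1.5 and 4, DESeq2's Wald test, limma-voom, a model without the other factor, and Spearman correlation. All entries of the deposited table entered the library sizes and 0 columns of other samples were present.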

Results

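Microvessels of primary rat vascular cells from subcutaneous soft connective tissue were cultured on a stiff or a soft extracellular matrix, without or with A83-01. A83-01 is a small-molecule inhibitor of the type I receptor kinases of TGF-beta. The mRNA of each of the 4 groups was sequenced as 1 library, so the series holds soft, soft with A83-01, stiff and stiff with A83-01. The stated aim was to learn what matrix stiffness and the inhibitor do to microvessels and to the conversion of pericytes, the mural cells of capillaries, into contractile, matrix-producing myofibroblasts. The labels give neither the stiffness values nor the dose.

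Total counts were 32475473 (soft), 32271844 (soft with A83-01), 33178552 (stiff) and 33416200 (stiff with A83-01). A floor of 3 counts corresponded to 0.0896, 0.0895, 0.103 and 0.0842 CPM, the usual count scaled to library size, in the same order. The gene for the collagen I chain Col1a1 took 4.05%, 1.82%, 6.09% and 2.04% of all counts, and the 10 most abundant genes of each library took 14%, 11.7%, 21.8% and 11.6%. Mitochondrially encoded transcripts held 4.72%, 6.35%, 3.86% and 5.59%. Both A83-01 libraries held the lower Col1a1 and the higher mitochondrial shares of their matrix. Of the deposited genes, 13634 reached the expression minimum and were compared. With 1 library per group, a difference between 2 libraries has no replicate check. The 95% intervals given for folds cover counting error only. No molecular identifiers are mentioned, so PCR copies may make these intervals too narrow even for that. A comparison of 2 libraries compares those libraries, not the conditions. Nothing in the labels says whether the libraries come from separate cultures or animals, so p-values measure only the spread between these libraries. The labels name both stiff libraries in a form that differs from that of both soft libraries, so stiffness and any separate preparation cannot be told apart in any stiffness value.

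Smooth muscle contractile genes were higher and cytokine and chemokine genes lower in the stiff than in the soft libraries, without and with the inhibitor. Acta2, the smooth muscle actin used to recognise myofibroblasts, stood at 271 CPM in the soft and 3691 CPM in the stiff library, 13.6-fold higher (13.3 to 13.9), with its 95% counting interval in parentheses. The neutrophil chemokine gene Cxcl6 stood at 114 CPM in the soft and 0.826 CPM in the stiff library, 128-fold lower (92.2 to 215). Stiffness was tested over all 4 libraries, 2 against 2, with the inhibitor as a block and 1 residual degree of freedom. In this additive model, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 320 genes up and 449 down on stiff matrix. Of these 769 genes, 767 moved in the same direction without and with the inhibitor. The residual of this model is the difference between those responses. The test therefore favours genes that agree, and this count is no separate check. DESeq2's Wald test called 574 up and 737 down. With scaling by total counts alone, the quasi-likelihood test called 623 up and 1135 down, and without the inhibitor in the model 13 up and 17 down.

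Contractile and myofibroblast genes rose on stiff matrix. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 13 of its 16 genes rose over all genes, and 16 rose adjusted over the list alone. Acta2 rose by 4.27 on the log2 scale (SE 0.360, adjusted p = 0.0125), and the actin-binding Tagln by 4.45 (SE 0.315, adjusted p = 0.00848) in the same quasi-likelihood test with Benjamini-Hochberg adjustment. Calponin, Cnn1, rose by 4.71 (SE 0.268). Smooth muscle myosin heavy chain, Myh11, rose by 5.24 (SE 0.210), and the actin Actg2 by 5.80 (SE 0.220). Myocardin, Myocd, a transcriptional coactivator of smooth muscle genes, rose by 3.35 (SE 0.362). Smtn, Cald1 and Srf did not pass over all genes. The list's median was 3.31 in stiff against soft and 3.14 with the inhibitor in both libraries, each in the top 2.5% of expression-matched random lists.

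Further genes that rose on stiff matrix encode adhesion proteins, matrix proteins and growth factors. The adhesion molecule Cntn2 rose by 6.46 (SE 0.192) and the matricellular Tinagl1 by 4.98 (SE 0.171). In the focal adhesion list, 5 of 17 genes rose over all genes, and 10 rose and 1 fell adjusted over the list alone. They included the collagen-binding integrin Itga11 (log2 2.85, SE 0.173) and the actin linkers Vcl (1.82, SE 0.184) and Actn1 (1.53, SE 0.172). Of 22 targets of the mechanosensitive coactivators YAP and TAZ, 4 rose over all genes, and 8 rose and 1 fell adjusted over the list alone. Ctgf, also a TGF-beta target, rose by 3.98 (SE 0.175) and Ajuba by 1.57 (SE 0.211). The list members Ankrd1 and Cyr61 did not pass, with log2 ratios of −0.16 and 0.45 in stiff against soft. Among 32 paracrine ligands, 4 rose and 6 fell over all genes, and 6 rose and 10 fell adjusted over the list alone. The TGF-beta isoform genes Tgfb3 (4.88, SE 0.189) and Tgfb2 (2.45, SE 0.129) and the Notch ligand Jag1 (1.11, SE 0.127) rose. The growth factor genes Hgf (−2.23, SE 0.280), Vegfd (−1.90, SE 0.186) and Angptl4 (−2.69, SE 0.247) fell. Pdgfb, the endothelial factor that recruits pericytes, and the endothelin gene Edn1 did not pass: their log2 differences in stiff against soft were −0.29 and 0.89.

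The fibrillar matrix list had 2 of 26 genes up and 2 down over all genes, and 7 up and 4 down adjusted over the list alone, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Col11a1, a chain of a minor fibrillar collagen, rose by 3.38 (SE 0.190), and Thbs2, a matricellular thrombospondin, fell by 1.85 (SE 0.243). Elastin, Eln, did not pass: it stood at 1.08 CPM in the soft and 66.3 CPM in the stiff library, 58.4-fold higher (44.4 to 88.3), and was 4.26-fold higher (3.34 to 5.75) with the inhibitor in both. Col1a1 and Col3a1, the main fibrillar collagens, were 1.77-fold (1.77 to 1.77) and 3.31-fold (3.30 to 3.32) higher in the stiff library and did not pass either. Of 17 matrix proteases and their inhibitors, 1 rose and 3 fell over all genes, and 3 rose and 7 fell adjusted over the list alone. The falling proteases included stromelysin, Mmp3 (−4.15, SE 0.390), and the gelatinase Mmp9 (−2.70, SE 0.340). For the 15 basement membrane genes the quasi-likelihood test called 0 over all genes and 0 adjusted over the list alone, while 3 were up and 1 down at unadjusted p of at most 0.05. DESeq2 called 3 up and 1 down there, and limma-voom 2 up and 0 down.

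Inflammatory genes fell on stiff matrix. Of the 20 cytokine, chemokine and adhesion genes, 16 fell over all genes and 19 fell adjusted over the list alone, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cxcl3 fell by 7.80 (SE 0.209, adjusted p = 0.00273) in that quasi-likelihood test with Benjamini-Hochberg adjustment, Il1a fell by 6.26 (SE 0.266), Il6 fell by 2.96 (SE 0.207) and the monocyte chemokine gene Ccl2 fell by 3.03 (SE 0.202). Csf3, the granulocyte growth factor gene, had 567 counts in soft and 0 in stiff, at least 164-fold lower, and 878 and 0 with the inhibitor. Tnf, Vcam1, Sele and Selp did not pass over all genes. The list's median was −3.31, and also −3.31 with the 2 zero-count members at the bound of their fold. Outside the list, the chemokine gene Ccl3 fell by 5.17 (SE 0.210) and the metallothionein Mt1 fell by 3.24 (SE 0.135). Among the genes lowest in the stiff library were secreted innate immune proteins: complement C3 was 582-fold lower (436 to 890), the antiprotease Slpi 586-fold lower (393 to 1208) and the siderophore-binding Lcn2 276-fold lower (235 to 337). These 3 genes also fell in the additive test.

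Markers of other cells moved alongside. Among 12 leukocyte and macrophage markers, 1 rose and 1 fell over all genes, and 2 rose and 5 fell adjusted over the list alone. The lysozyme gene Lyz2 rose by 3.28 (SE 0.380) and the MHC class II chain Cd74 fell, with 192 counts in soft and 0 in stiff, at least 55.6-fold lower. The most abundant member, Cd68, stood at 40.0 CPM in soft and 29.8 CPM in stiff. Of 9 adipocyte markers, 3 fell over all genes, and 1 rose and 7 fell adjusted over the list alone. They included the regulator Cebpa (−1.18, SE 0.145) and the adipsin gene Cfd (−1.74, SE 0.287), while Pparg, a regulator of fat cell formation, did not pass, with a log2 ratio of 0.47 in stiff against soft. Of 20 endothelial markers, 2 fell over all genes and 3 fell adjusted over the list alone: among them von Willebrand factor, Vwf (−1.69, SE 0.197), and Plvap (−1.13, SE 0.148). VE-cadherin, Cdh5, stood at 870 CPM in soft and 730 CPM in stiff. Pecam1 and Cldn5 were not analysed here.

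Pericyte and mural markers divided. Of 16, 3 rose and 1 fell over all genes, and 7 rose and 4 fell adjusted over the list alone, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Rgs5, a regulator of G-protein signalling abundant in pericytes, rose by 2.59 (SE 0.346), Rgs4 by 1.74 (SE 0.197) and the Notch target Heyl by 1.06 (SE 0.139). The PDGF receptor gene Pdgfrb and the proteoglycan gene Cspg4, which encodes NG2, did not pass: they were 1.28-fold (1.27 to 1.30) and 1.51-fold (1.43 to 1.59) higher in the stiff library. Of 15 fibroblast markers, 2 rose and 3 fell over all genes, and 2 rose and 4 fell adjusted over the list alone. Pdgfra (−2.18, SE 0.216) and the proteoglycan decorin, Dcn (−2.53, SE 0.404), fell, while Mfap5 (2.18, SE 0.167) and Ogn (2.81, SE 0.197) rose. Lymphatic endothelial markers, 6 in all, had 1 up and 1 down, the latter podoplanin, Pdpn (−1.52, SE 0.235), with the same counts adjusted over the list alone. Among 8 Schwann cell and nerve markers, the adhesion molecule Ncam1 rose (2.10, SE 0.331), the sole one adjusted over the list alone as well.

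Cholesterol synthesis genes rose and hypoxia and glycolysis genes fell. Of 16 cholesterol genes, 11 rose over all genes and 14 rose adjusted over the list alone, among them the synthase Hmgcs1 (1.19, SE 0.148) and the sterol oxidase Msmo1 (1.39, SE 0.135). Of 19 hypoxia and glycolysis genes, 5 fell over all genes and 13 fell adjusted over the list alone. The prolyl hydroxylase Egln3 fell by 2.70 (SE 0.248) and Bnip3 fell by 1.78 (SE 0.273). The TGF-beta response list of 16 genes had 1 up and 3 down over all genes, and 4 up and 4 down adjusted over the list alone. The falling members included the cytokine gene Il11 (−2.58, SE 0.359) and Ltbp2 (−1.80, SE 0.159). In stiff against soft without inhibitor, 9 of the 16 lay above 0 and 7 below. At 2-fold, 2 were higher, Tgfbi among them, and 3 lower. Of 9 BMP and ID response genes, Id1 fell (−1.65, SE 0.203), and 2 rose and 4 fell adjusted over the list alone. Smad7, the inhibitory SMAD, did not pass: it was 1.31-fold lower (1.15 to 1.5) in the stiff library. The Notch list of 13 had 3 up over all genes, and 3 up and 1 down adjusted over the list alone, Jag1, Heyl and Hes1 among them.

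Smaller groups of calls completed the lists. The 12 mesenchymal transition regulators had 1 up and 2 down over all genes, and 3 up and 3 down adjusted over the list alone, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Snai2 rose by 1.39 (SE 0.166), Twist2 fell by 1.47 (SE 0.192) and N-cadherin, Cdh2, fell by 1.31 (SE 0.160). Of 13 immediate early and heat shock genes, 3 rose and 1 fell over all genes, and 5 rose and 1 fell adjusted over the list alone. The nuclear receptor Nr4a1 fell by 3.05 (SE 0.281). The heat shock genes Hspa1a (2.07, SE 0.208) and Hspa1b (2.10, SE 0.203) are near-identical copies, so their separate counts are uncertain. For the 24 cell cycle genes the quasi-likelihood test called 0 over all genes and 8 up adjusted over the list alone. At unadjusted p of at most 0.05, 15 were up, while DESeq2 called 4 up and limma-voom 2 up. For the 14 interferon response genes it called 0 over all genes, 1 down adjusted over the list alone and 1 down unadjusted, with 1 down by DESeq2 and by limma-voom.

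Between the stiff and soft libraries without inhibitor, 727 genes were at least 2-fold higher on stiff and 1170 at least 2-fold lower, with a counting interval excluding equality. At 4-fold, 197 were higher and 401 lower. With total-count scaling, which moved the median of all genes by −0.232 on the log2 scale, the split was 528 higher and 1601 lower, or 24.8% higher in place of 38.3%. Unchanged groups simulated with the spread of the additive model gave on average 414 genes past 2-fold and 10 past 4-fold. The genes highest in the stiff library by the nearer interval bound included Actg2, Cntn2, Eln, Myh11, the cadherin gene Cdh20, C1qtnf3, Olr63 and Pmfbp1. Cdh20 had 0 counts in soft and 413 in stiff, at least 158-fold higher, and the secreted protein gene C1qtnf3 was 92.3-fold higher (66.3 to 161). The lowest included C3, Slpi, Lcn2, Csf3, Cxcl3, Cxcl2, the growth factor gene Gdf10 and coagulation factor V, F5. Gdf10 had 458 counts in soft and 0 in stiff, at least 133-fold lower, and F5 was 180-fold lower (104 to 750).

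**Figure D1:**
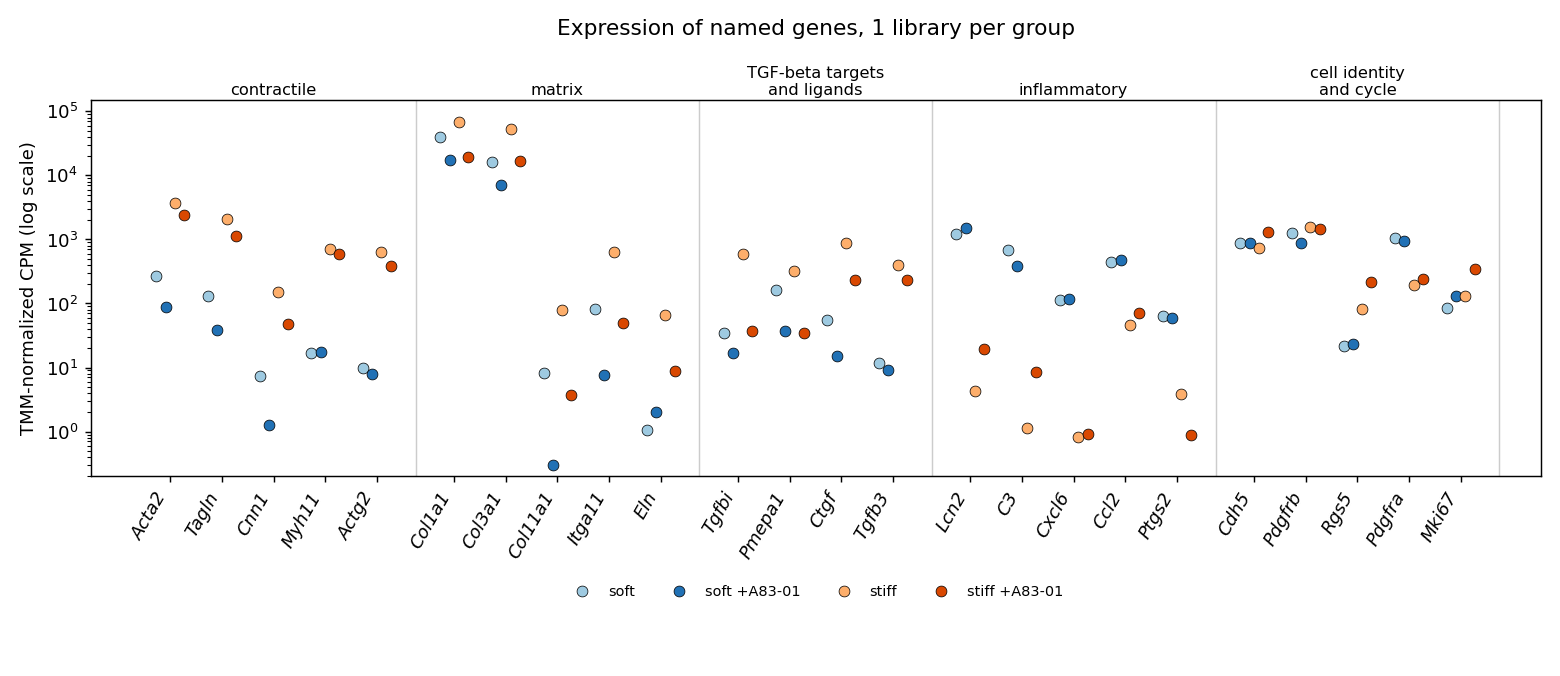
Expression of named genes in the 4 libraries, as TMM-normalised CPM on a log axis, 1 point per library, grouped in blocks of genes. Acta2 lies at 271 and 88.9 in the soft and at 3691 and 2428 in the stiff libraries (without and with A83-01), whereas Cxcl6 lies at 114 and 117 in the soft and at 0.826 and 0.926 in the stiff libraries.

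Stiffness was also compared with A83-01 present in both libraries. There 938 genes were at least 2-fold higher and 916 lower on stiff matrix, and 255 higher and 274 lower at 4-fold. Simulated unchanged groups gave 410 and 8.55. Acta2 was 27.3-fold higher (26.3 to 28.3), Tagln 29.4-fold higher (27.8 to 31.1) and Cnn1 36-fold higher (27.8 to 52.1). Ctgf was 15.6-fold higher (14.3 to 17.2) and Tgfb3 25.7-fold higher (23.1 to 29.1). Csf3 was at least 311-fold lower, Ptgs2, the inducible prostaglandin synthase, 61.2-fold lower (46.1 to 95.7) and Cxcl6 118-fold lower (89.6 to 183). Col1a1 was 1.08-fold higher (1.08 to 1.09). Smad7 was 1.52-fold lower (1.29 to 1.80), Pdgfrb 1.67-fold higher (1.65 to 1.69), Cspg4 1.43-fold higher (1.35 to 1.52), Edn1 1.74-fold higher (1.37 to 2.27) and the ratio of Pdgfb was 1.00-fold (0.967 to 1.04). The proliferation marker Mki67 was 2.59-fold higher (2.5 to 2.68), and 15 of 24 cell cycle genes were at least 2-fold higher. Among the highest genes, Dhrs7l1 and RT1-CE16 had counts in this stiff library alone (145 and 184). RT1-CE16 belongs to a family of near-identical MHC class I genes, and its count is uncertain. Olfml1 was 59.6-fold higher (37.6 to 173), and the chemokine gene Ccl22 had 146 counts in soft with A83-01 and 0 in stiff with A83-01, at least 51.8-fold lower.

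Across genes, log2 differences of stiff against soft without and with the inhibitor, which share no library, correlated with Pearson's r = 0.676 and Spearman's rho = 0.582. Genes are not independent replicates, and 4 such correlations were computed. At 2-fold, 377 genes were higher in both comparisons (50 expected for independent lists) and 603 lower in both (78.6 expected). Opposite directions were found for 13 and 14 genes.

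List medians described these library pairs further. In stiff against soft without inhibitor, 7 lists lay in the top 2.5% of 10000 random lists matched on expression. They were contractile (3.31), cholesterol synthesis (1.10), fibrillar matrix (0.661), focal adhesion (0.565), YAP and TAZ targets (0.361), pericyte and mural markers (0.298) and cell cycle (0.277). In the bottom 2.5% lay 9 lists: inflammatory (−3.31), adipocyte (−1.14), interferon (−0.89), hypoxia and glycolysis (−0.803), BMP and ID response (−0.502), leukocyte (−0.486), matrix proteases (−0.329), paracrine ligands (−0.274) and endothelial markers (−0.187). Total-count scaling, which moves the random lists as well, kept these 16 lists apart but gave smaller medians for fibrillar matrix (0.427), focal adhesion (0.331), YAP and TAZ targets (0.126), pericyte and mural markers (0.064) and cell cycle (0.0434). It gave lower ones for matrix proteases (−0.563), paracrine ligands (−0.508) and endothelial markers (−0.421). With the inhibitor in both libraries, 11 lists lay at the top. They were contractile (3.14), cell cycle (1.10), Schwann cell and nerve (0.894), pericyte and mural (0.805), fibroblast (0.787), cholesterol (0.772), focal adhesion (0.602), endothelial (0.509), YAP and TAZ targets (0.465), immediate early and heat shock (0.392) and Notch (0.356). At the bottom lay 6: inflammatory (−3.61), adipocyte (−1.22), hypoxia and glycolysis (−1.05), matrix proteases (−0.52), paracrine ligands (−0.386) and TGF-beta response (−0.344). Without inhibitor the remaining medians were those of TGF-beta response (0.172), basement membrane (0.0528), Notch (−0.0776), mesenchymal regulators (0.173), immediate early (0.251), fibroblast (0.068), lymphatic (−0.475) and Schwann cell lists (−0.278), the mean having the other sign for Notch (0.185), fibroblast (−0.096), lymphatic (0.16) and Schwann cell lists (0.0738). With total-count scaling or FPKM, those of TGF-beta response, basement membrane, mesenchymal regulators and fibroblast markers were negative. With the inhibitor they were BMP and ID response (−0.161), fibrillar matrix (0.0303), basement membrane (0.22), mesenchymal regulators (0.122, mean −0.0284, and a negative median at a minimum of 5 CPM), interferon (0.29), lymphatic (0.228) and leukocyte lists (−0.245). At a minimum of 5 CPM, the pericyte and mural list without and the adipocyte list with the inhibitor no longer stood apart. Skeletal muscle and keratinocyte markers had 4 and 3 members above the expression minimum, too few for a median.

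**Figure D2:**
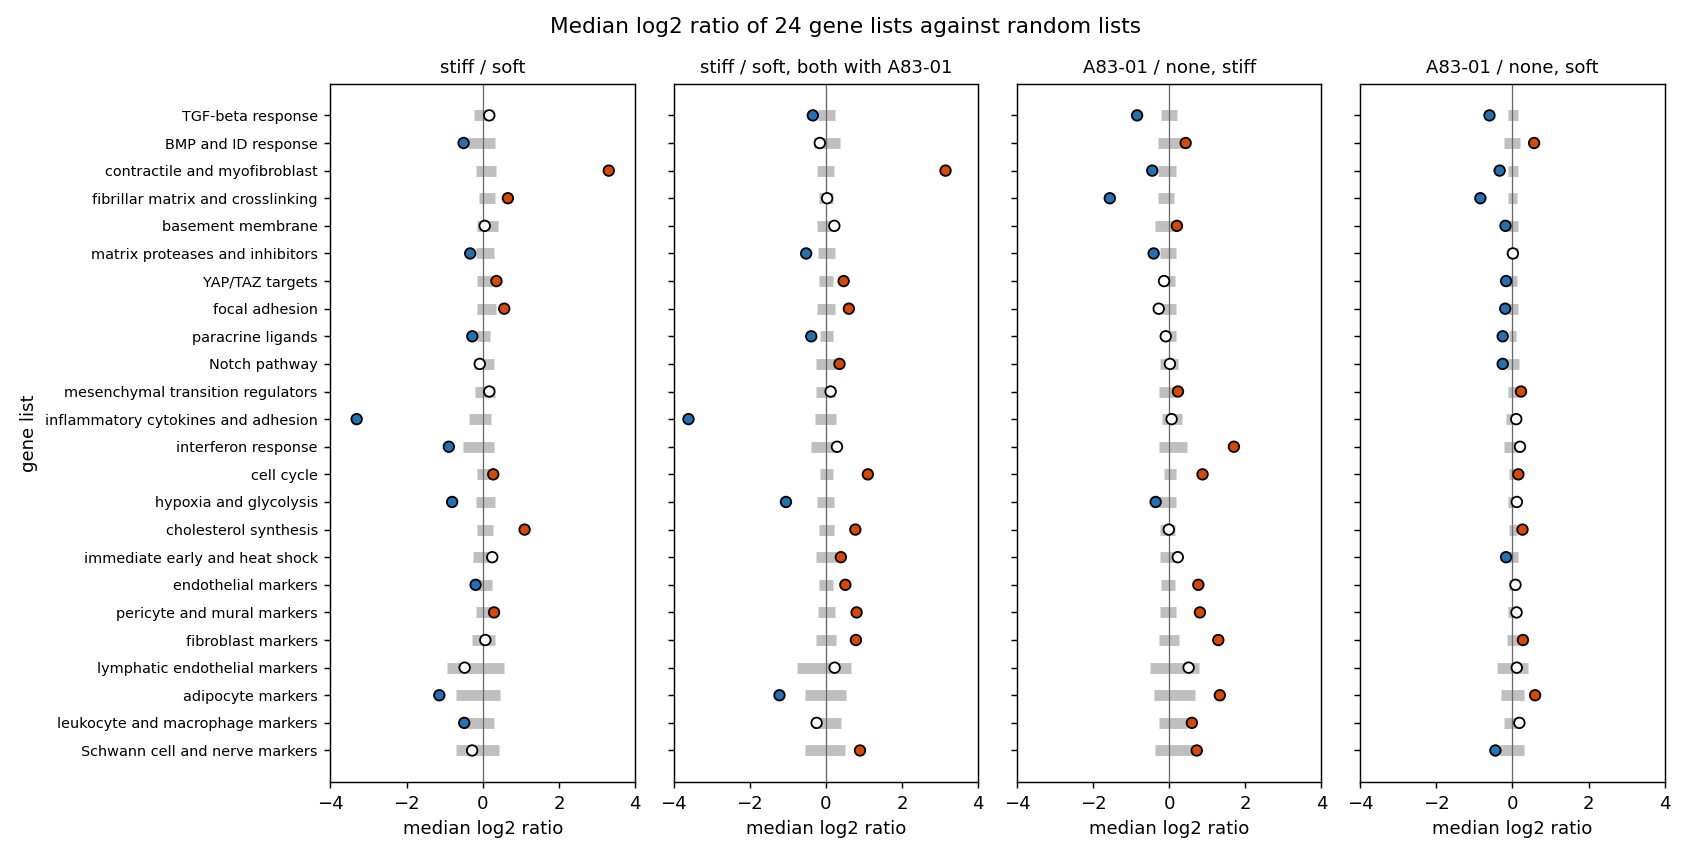
Median log2 ratio of each of 24 gene lists (points) in the 4 library pairs, 1 panel per pair, with a grey bar for the middle 95% of medians of expression-matched random lists. Orange points lie in the top 2.5% and blue points in the bottom 2.5%: the contractile list lies at 3.31 and 3.14 in the stiff against soft panels and at −0.445 and −0.335 in the A83-01 panels, and the fibrillar matrix list at −1.56 and −0.842 in the A83-01 panels.

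Few genes passed the additive test for A83-01, matrix and matrix-receptor genes among them. Between single libraries, 189 genes were at least 2-fold lower and 176 higher with A83-01 on both matrices, so few calls do not mean few shared differences. Over all 4 libraries, 2 against 2, with stiffness as a block, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 6 genes down and 0 up. At unadjusted p of at most 0.05, 989 genes were up and 823 down. DESeq2 called 219 up and 244 down, limma-voom 0 up and 3 down, and the quasi-likelihood test with total-count scaling 565 up and 270 down. With no expression filter it called 10 up and 17 down, and with DESeq2 size factors 0 down. An inhibitor response that differs between the matrices enters the residual of this model. The collagen gene Col11a1 fell by 4.51 (SE 0.196, adjusted p = 0.0327), the integrin gene Itga11 fell by 3.56 (SE 0.178, adjusted p = 0.0357) and the collagen gene Col8a2 fell by 3.58 (SE 0.209, adjusted p = 0.0377), all in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among the other calls were genes without a gene symbol: ENSRNOG00000045683 fell by 7.44 (SE 0.335) and LOC102553715 fell by 6.49 (SE 0.359). All 6 fell on both matrices, which this test favours because the difference between the matrices is its residual. Col11a1 stood at 8.10 CPM in soft and 0.298 CPM in soft with A83-01, and at 79.2 and 3.70 CPM on stiff.

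Of the 24 lists, 22 had no member that passed over all genes for the inhibitor, and fibrillar matrix and focal adhesion had 1 each down. In those 22 lists, between 0 and 8 genes were up and between 0 and 8 down at unadjusted p of at most 0.05, DESeq2 called between 0 and 6 up and between 0 and 4 down, and limma-voom called 0. Adjusted over the list alone, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave 17 of 26 fibrillar matrix genes and 8 of 16 TGF-beta response genes down. DESeq2 called 12 and 4 of them down over all genes, and limma-voom 1 and 0. Further falls adjusted over the list alone were 3 contractile genes, 2 Notch genes and 1 gene each of the focal adhesion, YAP and TAZ and Schwann cell lists. BMP and ID response genes gave 4 up, adipocyte markers 4 up and interferon genes 3 up. Fibroblast markers gave 6 up and 2 down, pericyte and mural markers 4 up and 2 down, matrix proteases 1 up and 2 down, and mesenchymal regulators 1 up and 1 down. Paracrine ligands, hypoxia genes and basement membrane genes gave 1 up each, and 7 lists gave 0. Those 7 were inflammatory, cell cycle, cholesterol, immediate early, endothelial, lymphatic and leukocyte genes. At unadjusted p of at most 0.05 they had 2, 8, 1, 1, 4, 2 and 2 genes up and 3, 0, 0, 3, 1, 0 and 1 down. DESeq2 called 1 inflammatory and 2 cell cycle genes up and 1 inflammatory and 1 endothelial gene down, and limma-voom 0.

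On stiff matrix, the library with A83-01 had lower fibrillar matrix and TGF-beta target transcripts and higher fibroblast, interferon and cell cycle transcripts. Col1a1 was 3.64-fold lower (3.63 to 3.65), Fbln2, which encodes the matrix glycoprotein fibulin, 123-fold lower (114 to 134), and Lrrc15, a marker of activated fibroblasts, 141-fold lower (104 to 237). The TGF-beta targets Tgfbi and Pmepa1 were 15.6-fold (14.8 to 16.5) and 9.33-fold (8.81 to 9.93) lower. Ctgf was 3.76-fold lower (3.67 to 3.85), Cnn1 3.10-fold lower (2.94 to 3.28) and Smad7 1.75-fold lower (1.49 to 2.07). Acta2 was 1.52-fold lower (1.51 to 1.53) and Tagln 1.86-fold lower (1.84 to 1.89). In all, 1064 genes were at least 2-fold higher and 609 lower, and 286 and 171 at 4-fold. Simulated unchanged groups gave 407 and 9.90. With total-count scaling, the median log2 ratio of all genes was 0.305 in place of 0.0232. There 1656 were higher and 393 lower, or 80.8% higher in place of 63.6%.

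Of 26 fibrillar matrix genes, 14 were at least 2-fold lower in this pair, and the median was −1.56. Lysyl hydroxylase, Plod2, was 13.8-fold lower (12.6 to 15.2), periostin, Postn, 6.78-fold lower (6.61 to 6.96) and lysyl oxidase, Lox, 6.01-fold lower (5.77 to 6.27). The tenascin gene Tnn was also among the lowest, and Prss35 was 71.5-fold lower (42.5 to 405) and Fibin 48.5-fold lower (34.3 to 90.0). C1qtnf3 stood at 66.2 CPM without and 0.337 CPM with A83-01, 167-fold lower (112 to 381). Sox9, a regulator of cartilage formation, had 257 counts without and 0 with A83-01, at least 105-fold lower, and Cpne4 100 and 0, at least 40.9-fold lower. Other lists in the bottom 2.5% were TGF-beta response (−0.843, 6 of 16 at least 2-fold lower), contractile (−0.445), matrix proteases (−0.408) and hypoxia and glycolysis (−0.355). With total-count scaling they stayed in the bottom 2.5%, at −0.56, −0.161, −0.124 and −0.0713. Collagenase, Mmp13, was 4.67-fold lower (3.53 to 6.73).

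Lists in the top 2.5% on stiff matrix with A83-01 were interferon response (median 1.70, 10 of 14 at least 2-fold higher), adipocyte (1.33), fibroblast (1.29), cell cycle (0.876) and pericyte and mural markers (0.807). Endothelial (0.766), Schwann cell and nerve (0.724), leukocyte (0.596), BMP and ID response (0.433), mesenchymal regulators (0.231) and basement membrane (0.203) were also there. With total-count scaling the last 3 stayed in the top 2.5%, at 0.715, 0.514 and 0.487. With zero-count members at the bound of their fold the adipocyte median was 1.29 and the interferon and leukocyte medians did not move. The interferon response gene Usp18 had 8 counts without and 72 with A83-01, 6.19-fold higher (3.53 to 17.6). The chemokine gene Cxcl10 was 7.12-fold higher (4.82 to 12.8) and the GTPase gene Gbp2 3.63-fold higher (3.20 to 4.16). All 24 cell cycle genes were above 0 and 9 were at least 2-fold higher, among them Mki67, 2.62-fold higher (2.52 to 2.71), and Cenpf, 3.07-fold higher (2.84 to 3.34).

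Of 15 fibroblast markers, 8 were at least 2-fold higher and 1 lower, with 10 above 0 and 5 below. Among those with the largest differences were Efemp1, an extracellular fibulin, 80.2-fold higher (61.7 to 116), Scara5, 8.41-fold higher (6.05 to 13.4), and Clec3b, 4.92-fold higher (4.30 to 5.73). Of 16 pericyte and mural markers, 5 were at least 2-fold higher and 1 lower. Rgs5 was 2.63-fold higher (2.52 to 2.76) and Notch3, the mural Notch receptor, 2.08-fold higher (2.04 to 2.12). In the Notch list of 13, however, 1 gene was at least 2-fold higher and 2 were lower. Vitronectin, Vtn, was 8.59-fold higher (6.18 to 13.7), whereas Pdgfrb was 1.08-fold lower (1.07 to 1.10), a direction that total-count scaling and the deposited FPKM turned, and Cspg4 1.47-fold lower (1.40 to 1.54). The endothelial receptor gene Tek was 2.65-fold higher (2.30 to 3.07), Egfl7 2.43-fold higher (2.28 to 2.60) and Cdh5 1.82-fold higher (1.79 to 1.85). Edn1 was 1.58-fold lower (1.30 to 1.94) and Pdgfb 1.06-fold lower (1.02 to 1.10), the latter again turned by total-count scaling and FPKM. Id1 was 2.37-fold higher (2.02 to 2.82) and Id4 2.36-fold higher (2.08 to 2.70). The chemokine gene Cxcl12 stood at 41.0 CPM without and 665 CPM with A83-01, 16.2-fold higher (15.3 to 17.2). Sectm1b was 225-fold higher (163 to 372), Myo7b 110-fold higher (61.3 to 580) and the retinoic acid-binding Crabp1 68.9-fold higher (40.6 to 243). Gdf10, Kng1 and Pvalb had 0 counts on stiff without A83-01 and 305, 524 and 209 with it, at least 82.9-fold, at least 142-fold and at least 56.8-fold higher. RT1-CE16, uncertain as above, had 184 and was at least 50.0-fold higher.

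Medians in the middle of the random lists for stiff with A83-01 were those of inflammatory genes (0.0637, with 4 at least 2-fold higher and 2 lower), YAP and TAZ targets (−0.135), focal adhesion (−0.275), paracrine ligands (−0.0903), Notch (0.0193), cholesterol synthesis (−0.0095), immediate early (0.226) and lymphatic endothelial genes (0.51). The mean had the other sign for paracrine ligands (0.00174), Notch (−0.188) and cholesterol synthesis (0.00191). With total-count scaling or FPKM, the medians of YAP and TAZ targets, focal adhesion, paracrine ligands and cholesterol synthesis were positive. Among the paracrine ligands, Igf1 was 10.9-fold higher (8.79 to 14.3) and the neuregulin gene Nrg1 20.3-fold lower (13.4 to 46.8). Vcam1, the endothelial adhesion molecule gene, was 13.6-fold higher (10.8 to 18.4).

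On soft matrix, A83-01 was accompanied by fewer differences, with lower matrix genes among the largest. Lrrc15 was 24.1-fold lower (17.2 to 41.5), Col11a1 22.7-fold lower (14.5 to 57.2), Fibin 19.6-fold lower (13 to 42.9), Fbln2 14.5-fold lower (13.1 to 16.4), fibrillin Fbn2 13.7-fold lower (9.55 to 24.9) and Itga11 10.5-fold lower (9.29 to 12.1). Tnn was among the lowest as well, and Cfap53 had 55 counts without and 0 with the inhibitor, at least 18.4-fold lower. Col1a1 was 2.23-fold lower (2.23 to 2.24), Ctgf 3.71-fold lower (3.37 to 4.11) and Pmepa1 4.42-fold lower (4.16 to 4.71). Acta2 was 3.05-fold lower (2.92 to 3.18), Tagln 3.39-fold lower (3.19 to 3.62) and Cnn1 5.60-fold lower (4.20 to 8.24). Smad7 was 1.51-fold lower (1.32 to 1.73). The highest genes included Mlana, 22.9-fold higher (13.3 to 99.2), Efemp1, 13.8-fold higher (11.5 to 17.5), the aldehyde dehydrogenase Aldh3a1, 16.4-fold higher (10.8 to 35.7), and Clec3b, 9.41-fold higher (7.99 to 11.4). In all, 297 genes were at least 2-fold higher and 332 lower, and 54 and 62 at 4-fold. Simulated unchanged groups gave 399 and 8.50.

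On soft matrix with A83-01, 10 lists lay in the bottom 2.5%. They were fibrillar matrix (−0.842, 10 of 26 at least 2-fold lower), TGF-beta response (−0.602, 4 of 16), Schwann cell and nerve (−0.447), contractile (−0.335, 3 of 16), paracrine ligands (−0.255), Notch (−0.255), focal adhesion (−0.189), basement membrane (−0.182), immediate early and heat shock (−0.167) and YAP and TAZ targets (−0.166). The mean of the basement membrane list had the other sign, 0.0264. The YAP and TAZ list no longer stood apart at a minimum of 5 CPM, nor did the fibroblast list with the deposited FPKM. In the top 2.5% lay adipocyte (0.596), BMP and ID response (0.57), fibroblast (0.277), cholesterol synthesis (0.265), mesenchymal regulators (0.226) and cell cycle (0.157). The 8 others lay between, namely matrix proteases (0.012), inflammatory (0.101), interferon (0.199), hypoxia and glycolysis (0.116), endothelial (0.0812), pericyte and mural (0.109), lymphatic (0.115) and leukocyte (0.183). For matrix proteases (−0.0335) and endothelial markers (−0.0119) the mean was negative. Id1 was 1.58-fold higher (1.45 to 1.72), Rgs5 1.06-fold higher (0.957 to 1.18), Pdgfrb 1.41-fold lower (1.39 to 1.43), Cspg4 1.39-fold lower (1.31 to 1.48), Cdh5 1.02-fold higher (1.00 to 1.03), Mki67 1.55-fold higher (1.48 to 1.63), and Edn1 1.48-fold lower (1.15 to 1.95). Pdgfb had a log2 ratio of −0.37.

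Responses to A83-01 on the 2 matrices, from pairs that share no library, correlated across genes with r = 0.508 and rho = 0.403. At 2-fold, 176 genes were higher in both (23.2 expected for independent lists), 189 lower in both (14.8 expected), and 16 and 11 opposite.

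**Figure D3:**
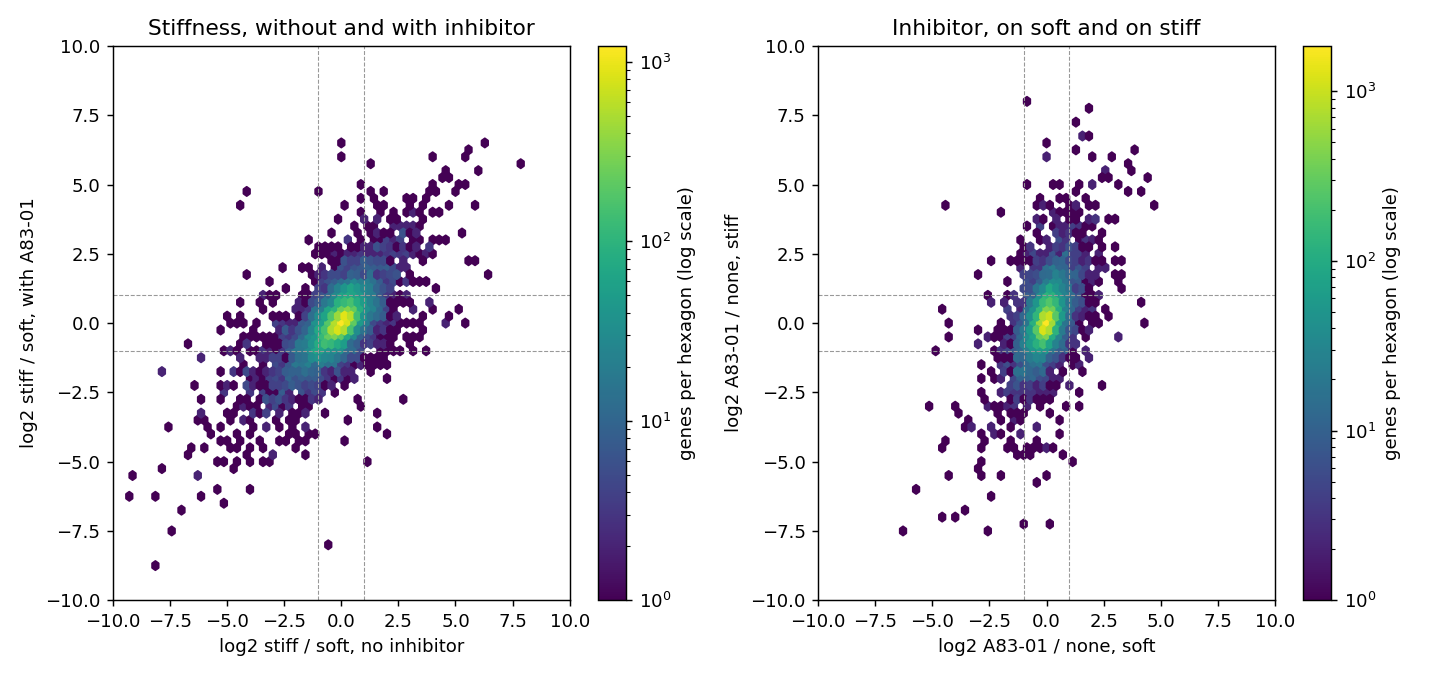
Log2 ratios of 13634 genes in pairs of comparisons that share no library, as hexagons coloured by the number of genes on a log scale, with dashed lines at 2-fold. The left panel sets stiff against soft without the inhibitor (x axis) against the same with it (y axis, r = 0.676), and the right panel sets A83-01 against none on soft (x axis) against the same on stiff (y axis, r = 0.508).

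The response on stiff minus the response on soft is a value without a test, since no residual degree of freedom is left. It was at least 2-fold positive for 854 genes and negative for 436, and at 4-fold for 211 and 92. With total-count scaling, its median was 0.294 in place of 0.0229, and the numbers were 1486 and 267, or 84.8% positive in place of 66.2%. Sectm1b with a log2 difference and counting interval of 5.99 (5.45 to 6.54), the chemokine gene Cxcl14 with 4.53 (4.26 to 4.81) and the growth factor gene Ptn with 4.46 (4.24 to 4.69) were among the most positive, with Kng1 and Gdf10. In the stiff library Cxcl14 and Ptn stood at 4.27 and 6.98 CPM, against 46.7 and 57.6 in soft and 81.6 and 135 in stiff with A83-01. Among the most negative were Eln with −3.78 (−4.37 to −3.18), Cyp2s1 with −4.14 (−5.10 to −3.18) and Cobl with −3.86 (−4.58 to −3.14), beside Sox9 and Cpne4. For Acta2, Tagln and Cnn1 the difference was 1.00 (0.94 to 1.06), 0.86 (0.77 to 0.95) and 0.85 (0.39 to 1.32), and for Col1a1 −0.71 (−0.71 to −0.70). Over all genes, stiffness, inhibitor and their interaction held 58.5%, 30% and 11.5% of the sum of squares of log2 CPM contrasts.

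Stiff against soft and A83-01 on stiff share the stiff library. Their log2 ratios correlated across genes with r = −0.481 and rho = −0.421, and unchanged groups simulated with the shared library gave r = −0.508. The covariance was −0.367, against −0.0966 simulated, a difference of −0.27. Of the genes at least 2-fold higher on stiff, 252 were at least 2-fold lower with A83-01 (32.5 expected for independent lists, 34.2 simulated), Fbln2, C1qtnf3, Tnn and Tgfbi among them. Of the genes lower on stiff, 403 were higher with A83-01 (91.3 expected, 67.2 simulated), Cxcl12, Sectm1b and Gdf10 among them. The simulated groups had on average 414 and 407 genes past 2-fold, against 1897 and 1673 observed. The simulated overlaps therefore do not give what a shared library yields for lists of the observed size. The single stiff library cannot be split, so how much of the overlap comes from sharing it cannot be told. The orthogonal stiffness and inhibitor contrasts over all 4 libraries correlated with r = −0.207 and rho = −0.141. Both contrasts hold the stiff library, with opposite signs. A deviation of that library alone would also make this correlation negative, so it is no check free of the sharing.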

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

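The test of mural cell share was chosen only after the result was seen. The 3 tests on the numbers of genes responding to the inhibitor were chosen before.

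Opposite directions in the paired comparisons drew attention to 2 genes and 3 gene lists, and none of these differences was tested. The neuregulin gene Nrg1 had a log2 ratio of 1.95 in stiff against soft without inhibitor and −2.10 with it, a difference of 4.05. The glucose transporter gene Slc2a4 had −1 without and 1.04 with the inhibitor, a difference of −2.04. The endothelial marker list had a median of −0.187 without and 0.509 with the inhibitor, a difference of −0.695. For the inhibitor, the basement membrane list had a median of 0.203 on stiff and −0.182 on soft matrix, a difference of 0.385, and the Schwann cell and nerve list 0.724 and −0.447, a difference of 1.17.

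More genes were at least 2-fold apart between the libraries without and with A83-01 on stiff (1673) than on soft matrix (629), a ratio of 2.66. The tables argue against the scaling of the libraries as a likely cause, since the smallest ratio under 3 other scalings was 2.64. They also argue against genes near the detection floor, since the ratio was 3.30 among the 9034 genes with a mean of at least 10 CPM. A deviation of 1 library cannot be told apart from a larger response on stiff matrix, because the 1290 genes at least 2-fold apart in the difference of responses rest on 1 library per group. A response that depends on stiffness stays open and untested.

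Contractile genes were higher in the stiff library, with a list median of 3.31 and a bootstrap interval over members of 2.18 to 4.01. Pericyte and mural markers had a median of 0.298 (−0.295 to 0.594), which argues against an equal rise of all mural cells as the whole cause. Both intervals are over genes of 1 library pair and hold no spread between libraries. The mural genes Rgs5, Rgs4 and Heyl did rise with stiffness, so a higher share of some mural cells stays open. A higher share of smooth muscle cells stays open as well, because their markers are the contractile genes themselves. An effect of stiffness on these genes within cells also stays open, as does a separate preparation of the stiff libraries, whose label names differ in form from those of the soft ones.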

How the results depend on the processing

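All alternatives were chosen before the data were examined, so no test in this part was chosen after the result was seen. No paired analysis was possible because the labels pair no libraries by replicate; the additive model used the other factor as its block. Leaving out a library was not run, since the additive model then has no residual degree of freedom. Genes with few counts are limited by depth, with 3 counts at 0.0842 to 0.103 CPM.

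Of 472 list medians under the alternatives, 465 kept their place among random lists, 4 no longer stood apart, 3 newly did, and 0 of those standing apart changed sign. Of the medians that did not stand apart, 17 changed sign, 8 each with total counts only and with FPKM and 1 at a minimum of 5 CPM. Of 1458 values of named genes, 1396 kept their call or lack of one, 30 lost the call, 32 gained it, and 0 with a call changed sign. Of those without a call, 8 changed sign, 4 each with total counts only and with FPKM. The counts of genes and the correlations that moved are as follows, each pair of counts giving higher and then lower. Fewer or more genes were counted by construction under the fold thresholds and filters, and for the others the cause was not tested.

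With total counts only, the inhibitor on stiff gave 1656 and 393, the difference of responses 1486 and 267, the stiffness test 623 and 1135 and the inhibitor test 565 and 270. With no filter, the inhibitor on soft gave 506 and 558 and the inhibitor test 10 and 17. At a minimum of 5 CPM, stiff against soft gave 484 and 717, the inhibitor on soft 174 and 210 and the difference of responses 510 and 263, while 683 genes were higher with the inhibitor on stiff and 570 lower in stiff against soft with the inhibitor. With the authors' FPKM, 484 genes were higher in stiff against soft, 358 lower with the inhibitor on stiff, and the difference of responses gave 1440 and 252.

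At a fold threshold of 1.5, stiff against soft gave 1490 and 2121, the inhibitor on stiff 2048 and 1360, the inhibitor on soft 767 and 812, stiff against soft with the inhibitor 1836 and 1784, and the difference of responses 1767 and 1024. At a fold threshold of 4, these were 197 and 401, 286 and 171, 54 and 62, 255 and 274, and 211 and 92.

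DESeq2's Wald test gave 574 and 737 for stiffness and 219 and 244 for the inhibitor. For the inhibitor, limma-voom gave 3 lower genes and edgeR's quasi-likelihood test with DESeq2 median-ratio size factors 0, beside 989 up and 823 down at unadjusted p in the reported test. With the other factor not in the model, stiffness gave 13 and 17 and the inhibitor 0 lower genes.

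Across genes, stiffness without and with inhibitor correlated with 0.721 at 5 CPM, 0.692 at prior count 10 and 0.582 by Spearman. The inhibitor on stiff and on soft correlated with 0.593, 0.529 and 0.403 under the same settings. Stiffness and the inhibitor on stiff gave −0.460 at prior count 10, −0.449 with FPKM and −0.421 by Spearman. The stiffness and inhibitor contrasts gave −0.238 at 5 CPM, −0.183 with FPKM and −0.141 by Spearman.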

Other observations

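The test of leukocyte share was chosen only after the result was seen. The genes given here as values were chosen after those values were seen. Adgre1 lies beyond the lists and the named-gene rule, while Adm belongs to the hypoxia and glycolysis list and Dcn to the fibroblast list. The macrophage gene Adgre1 stood at 24.5 CPM in soft, 37.4 in soft with A83-01, 0.447 in stiff and 2.38 in stiff with A83-01, and on stiff matrix its log2 level fell by 4.64 (SE 0.445) in edgeR's quasi-likelihood test. The vasodilator peptide gene Adm stood at 121, 250, 20.7 and 153 CPM in the same order, and decorin, Dcn, at 11520, 21950, 1442 and 5279 CPM.

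Inflammatory genes were lower in the stiff library, with a list median of −3.31 and a bootstrap interval over members of −5.32 to −2.48. The 12 leukocyte and macrophage markers had a median of −0.486 (−1.23 to 0.0742), which argues against an equal loss of all leukocytes as the whole cause. Both intervals are over genes of 1 library pair and hold no spread between libraries. The most abundant of these markers, Cd68, stood at 40.0 CPM in soft and 29.8 in stiff, and Lyz2 was higher in stiff (1.58 and 23.5 CPM). Cd74, with 192 and 0 counts, and Adgre1 went with the inflammatory genes, so loss of a subset of leukocytes stays open. An effect of stiffness on vascular cells and a separate preparation of the stiff libraries stay open as well.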
